A study of Mus musculus with 2 samples.

How the data were processed

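Thymic stroma of mice labelled E2F_M11 was profiled by droplet single-cell RNA sequencing with the 10x Genomics 3' chemistry in 2 libraries. In E2F_M11, 2 E2F binding sites of the Foxn1 proximal promoter were removed with CRISPR-Cas9, per the labels. The thymi were digested with collagenase/dispase and DNase, red cells were lysed, and CD45-positive blood cells were depleted on magnetic beads, per the labels' protocols. That depletion sets the share of thymocytes and other blood cells. The labels do not say that the libraries came from separate animals. With the library as a block, p-values measure how differences between classes vary between these libraries, over all 10 classes. That spread may be technical. The wild-type stromal data to which the study compared these libraries were not analysed here, so no value measures the effect of the deletion.

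The authors deposited raw UMI counts per gene and barcode, with no normalisation. The submitters' processing notes name Cell Ranger 7, Seurat 4 and the mouse build mm10, whereas the matrices name Cell Ranger 6.0.0, per the file headers. Each matrix held 32285 features. Filters that the authors applied to barcodes are not given in the sources used here. Gene positions were taken from GENCODE annotation of GRCm38 by the gene identifier in the files.

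Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept. This left 3588 of 5110 barcodes of library 1 and 8186 of 19163 barcodes of library 2. Doublets were sought with Scrublet in scanpy 1.11.5 at an expected rate of 6%. It called 1 cell in library 1 (0.0279%) and 0 in library 2, so the caller did not work on these data and doublets remain in the classes. The 1 called cell was removed, which left 11773 cells.

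Counts were scaled to 10000 per cell and log transformed. The 2000 most variable genes seen in at least 1% of cells were scaled to a maximum of 10, reduced to 30 principal components and clustered over 15 neighbours with the Leiden method at resolution 1. Mitochondrial genes and the 191 genes of the fixed lists were held out of this step. No correction between libraries was applied. The minimum of 1% and the scaling were chosen after other versions had been seen, and those versions are among the alternatives.

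The 47 clusters were named from markers of 20 cell types fixed before the data were examined. The scoring rule was written afterwards. A marker counted as raised at a log2 fold of 1 over the median cluster and detection in 10% of the cluster's cells. A name needed 3 raised markers, 60% of the type's markers raised (not asked of the mimetic types other than tuft and keratinocyte), a mean log2 fold of 2 for epithelial types or 1 for others, and a margin of 1 over the next type of its lineage. Clusters with over 50% of the markers of another lineage raised, with under 50 cells, with leading genes of another type, or with a UMI number low against the median cell of the same library and no own marker among the 10 leading genes stayed unnamed. The limit of 50 cells was set after a small fibroblast-like cluster had been seen. In all, 19 clusters were named and fell into 10 classes. The unnamed cells were 20.1% of library 1 and 45.3% of library 2. Clusters mixing lineages held 1.62% and 23.7%, clusters without enough raised markers 3.99% and 13.9%, clusters that qualified for 2 types 11.5% and 3.71%, clusters of low UMI number 2.56% and 0.586%, and small clusters 0.446% and 3.44%.

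The mTEC-like class joined 3 clusters. A Ccl21a-high cluster had 378 and 135 cells in libraries 1 and 2. A first Aire-high cluster had 409 and 167 cells, and a second 115 and 402 cells. In both Aire-high clusters the 10 leading genes held 1 medullary marker (Aire), 1 macrophage marker (Lyz2) and 1 neutrophil marker (S100a8). They were kept because no single other type had more markers there, and each result was also computed without them. From the description of the clusters 1 leading gene is left out on purpose.

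Raw counts were summed per library and class, which gave 20 sums. They were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test, with TMM scaling, filterByExpr and the library as a block, since each library holds every class. The fit covered 11944 genes with 9 residual degrees of freedom and a common biological coefficient of variation of 0.232. The 3 comparisons were cTEC-like against mTEC-like, the mean of both against fibroblast-like, and that mean against endothelial-like cells. A gene was called at a Benjamini-Hochberg adjusted p at or under 0.05 over all genes, and counts adjusted over the list alone are given beside this. SE is the log2 fold divided by the root of F. The 7 gene lists share no gene and were fixed before the data were examined, and 178 of their 191 genes passed the filter. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated correlation, and with fry, adjusted over 21 tests. In simulated counts for cTEC-like against mTEC-like cells over 11944 genes, 82 of 100 genes changed 4-fold and 11 of 100 changed 2-fold were recovered. None had the wrong sign, and 4 unchanged genes were called (4.12% of calls). Each gene was drawn alone around the means of the additive fit. Correlation between genes and class differences that vary jointly with the library were absent, so these rates may not hold for the real counts.

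Named genes were fixed by rule: Foxn1, Rb1 and E2F genes passing the filter, and from each list up to 3 called genes with the largest fold in each direction that moved alike in both libraries. Fold changes against a group with 0 counts were computed from pooled counts against 3 counts over the group, and those against 1 to 3 counts carry an exact 95% counting interval. H2-Q7 and Hspa1a have near-identical relatives, and their counts are uncertain to that extent.

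Levels are CPM, a gene's share of all UMIs of the summed cells of a class. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, which left out no cell, with exact binomial 95% intervals that cover counting error only. For a share of 0 the limit given is 3 cells over the number of cells, not the exact interval. A cell was scored for G2/M genes at 2 or more UMIs over that list. Alternatives were DESeq2 1.42.0 size factors and its Wald test, no low-count filter, no library block, looser and stricter cell filters (300 genes, 500 UMIs and 20%, or 1000 genes, 2000 UMIs and 5%), resolutions of 0.5 and 2, doublets kept, list genes kept in the clustering, each library clustered alone, unthinned cells, 1 or 3 G2/M UMIs, stromal cells as denominator, and each library alone. The 4 added after seeing the data were clustering without scaling, clustering without the 1% minimum, removal of the cells with the highest doublet scores, and the mTEC-like class without its Aire-high clusters.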

Results

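Total thymic stroma depleted of CD45-positive cells was sequenced from the thymus of E2F_M11 mice, in which 2 E2F sites of the Foxn1 promoter were deleted. FOXN1 is the transcription factor that drives thymic epithelial differentiation, and E2F factors control genes of the G1 to S step of the cell cycle. The series addresses how E2F proteins affect thymic size. Library 1 held 41075328 UMIs in 5110 barcodes and library 2 held 42583831 UMIs in 19163 barcodes. After filtering, the median cell had 8727 UMIs in library 1 and 1874 in library 2. As both libraries share 1 genotype, the comparisons set cell classes of the E2F_M11 thymus against each other, with the libraries as replicates (n = 2).

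Foxn1 (ENSMUSG00000002057, GRCm38 chromosome 11, 78357577 to 78386558, minus strand) was detected in the epithelium of both libraries. In cTEC-like cells, the cortical epithelium that supports early thymocytes, its level was 281 CPM in library 1 and 133 CPM in library 2 (mean 207 ± 104, SD, n = 2). In mTEC-like cells, the medullary epithelium, it was 94.2 and 116 CPM (105 ± 15.4, SD, n = 2). Keratinocyte-like mTEC had 131 and 56.5 CPM, tuft-like mTEC 18.8 and 35.3 CPM, and other mimetic-like cells 11.4 and 24.4 CPM. Fibroblast-like cells had 0.859 and 0.391 CPM, from 11 and 2 UMIs. The endothelial-like value of library 2, 17.5 CPM, came from 8 UMIs in 2 cells, and library 1 had 0. These 3' tags lie outside the deleted promoter sites and check nothing about the deletion.

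At 1000 UMIs per cell, a Foxn1 UMI was found in 22.9% of cTEC-like cells of library 1 (exact 95% interval 14.4 to 33.4) and 9.82% in library 2 (5.72 to 15.5). The mTEC-like shares were 6.65% (5.11 to 8.48) and 5.82% (4.21 to 7.82). Fibroblast-like cells, which should lack Foxn1, had 0.147% in library 1 and 0 of 736 cells in library 2, which allows a share of up to 0.408%. Unthinned shares were 74.7% and 25.8% for cTEC-like, 35.8% and 25.6% for mTEC-like, and 0.736% and 0.272% for fibroblast-like cells. The median UMIs per cell were 16228 and 2012 for cTEC-like, 10495.5 and 2512.5 for mTEC-like, and 8736 and 6589 for fibroblast-like cells. The excess of cTEC-like over mTEC-like cells held in library 1, while in library 2 the intervals overlapped.

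**Figure D1:**
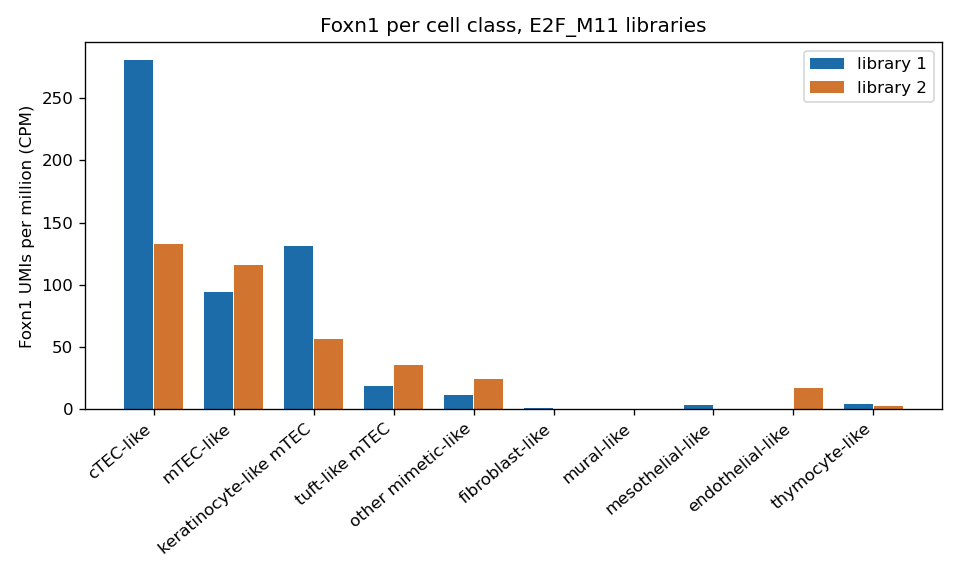
Foxn1 level in CPM per cell class, with 1 bar per library and no error bar, since each bar is a single library. The cTEC-like bars stand at 281 and 133 CPM and the mTEC-like bars at 94.2 and 116 CPM, while fibroblast-like bars lie under 1 CPM.

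As named here, the cTEC-like class took a similar share of both libraries, whereas the other large classes did not. It held 83 of 3587 cells of library 1 (2.31%, exact 95% interval 1.85 to 2.86) and 163 of 8186 cells of library 2 (1.99%, 1.70 to 2.32). The mTEC-like share was 25.1% and 8.60% (16.9% ± 11.7, SD, n = 2), and the fibroblast-like share 37.9% and 8.99% (23.4% ± 20.4). Thymocyte-like cells made up 3.90% and 25.1% (mean 14.5%). Endothelial-like cells were 2.51% and 1.77%, mesothelial-like cells 3.04% and 0.428%, and mural-like cells, the pericytes and smooth muscle, 1.48% and 0.476%. Tuft-like mTEC were 1.87% and 3.12%, keratinocyte-like mTEC 0.892% and 2.94%, and other mimetic-like cells 0.836% and 1.31%. Of stromal cells alone, cTEC-like cells were 2.41% and 2.66%, and mTEC-like cells 26.2% and 11.5%. The CD45 depletion sets the thymocyte-like share, the lower UMI number of library 2 can move every share, and 20.1% and 45.3% of cells stayed unnamed. Unnamed clusters mixing 9 of 9 raised fibroblast markers with thymocyte markers held 12.0% and 3.25% of library 2. They held 0.585% and 0.0836% of library 1, so the naming rule bears on the fibroblast-like difference. The mean cTEC-like share ran from 1.39% to 4.67% over the alternatives, the fibroblast-like share from 23.4% to 41.0% and the mTEC-like share from 6.09% to 18.8%. With each library clustered alone, no cTEC-like cells were found in library 1.

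The first comparison asked how the cortical and medullary epithelium of the E2F_M11 thymus differ in the genes of thymopoiesis and of the E2F network. Several genes that attract or instruct T cell progenitors were higher in cTEC-like cells. Cxcl12, a chemokine for progenitors, stood 5.01 log2 units higher (SE 0.650, edgeR adjusted p = 5.05e-05), Ccl25, a second such chemokine, 4.14 (SE 0.5998), and Pax1, a transcription factor of pharyngeal endoderm, 3.44 (SE 0.416). Ccl19, a chemokine of the medulla, was lower by a log2 fold of -4.13 (SE 0.588), Fgf21 by -4.20 (SE 0.740), and Cd40, the TNF family receptor that receives T cell help, by -1.52 (SE 0.349, edgeR adjusted p = 0.00475). The Cd40 call was kept in 9 of 13 alternatives, and its log2 fold turned to 1.65 without the Aire-high clusters. Foxn1 itself was not called: its log2 fold was 0.87 (SE 0.454, edgeR adjusted p = 0.195), with 1.49 in library 1 and 0.07 in library 2.

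Of the 23 tested genes for thymopoiesis and epithelial identity, 7 were higher and 3 lower in cTEC-like cells (11 adjusted over the list alone). The higher genes also included Dll4, the Notch ligand for T lineage commitment (2.90), Kitl (2.76), Jag2 (1.77) and Il7 (1.35), which fell outside the rule for named genes and were chosen after their values were seen. Camera placed this list above the other genes (adjusted p = 4.18e-04, and adjusted p = 0.143 with an estimated correlation). Thymocyte markers summed to 1465 and 2023 CPM in cTEC-like cells against 142 and 518 CPM in mTEC-like cells.

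Of 25 genes of the E2F and Rb network, 3 were higher and 6 lower (10 adjusted over the list alone). Tfdp2, a DNA-binding partner of E2F proteins, was higher by 1.83 (SE 0.314), Ccnd3, a D cyclin, by 1.37 (SE 0.370), and Cdkn2d, an inhibitor of Cdk4 and Cdk6, by 1.17 (SE 0.307). Other cyclin-dependent kinase inhibitors among the called genes were lower, among them Cdkn2b by -3.59 (SE 0.510), Cdkn1c by -3.72 (SE 0.942) and Cdkn2a by -4.50 (SE 0.802). Cdkn2b turned to 0.34 without the Aire-high clusters, Cdkn1c to 0.69 at resolution 0.5 and 0.53 under looser cell filters, and their calls were kept in 9 and 7 of 13 alternatives. The Cdkn2d call was kept in 9 of 13 alternatives, with a log2 fold down to 0.71. Thymocyte markers stood at 1465 and 2023 CPM in cTEC-like against 142 and 518 CPM in mTEC-like cells. Thymocyte RNA as a part of the Tfdp2, Ccnd3 and Cdkn2d values was not tested. No E2F factor was called: E2f4 stood at 0.71, E2f6 at 0.66, E2f2 at 0.63, E2f8 at 0.62, E2f3 at 0.10 and E2f5 at -0.80, and Rb1 at -0.09. E2f1 and E2f7 did not pass the low-count filter. The list's median (0.10) and mean (-0.49) differed in sign, and camera did not separate it (adjusted p = 0.894).

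Of 32 G1/S replication genes edgeR called 0 (0 adjusted over the list alone, 2 at an unadjusted p under 0.05), and DESeq2 called 0. Of 28 G2/M genes edgeR called 0 (0 adjusted over the list alone, 0 at an unadjusted p under 0.05), and DESeq2 called 0. The libraries went apart for the G2/M genes: 0 of 28 were higher in cTEC-like cells in library 1, with a median log2 fold of -1.28, and 28 of 28 in library 2, with a median of 1.09. For both lists camera gave the direction up (adjusted p = 0.820 for G1/S and 0.894 for G2/M), whereas fry, the medians (-0.06 and -0.19) and the means (-0.18 and -0.12) pointed down.

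Among 21 genes of antigen presentation, 3 were higher and 5 lower in cTEC-like cells (8 adjusted over the list alone). Psmb9 (1.63, SE 0.326) and Psmb10 (1.17, SE 0.349), subunits of the immunoproteasome, and H2-DMa (0.93, SE 0.316), which loads peptide on MHC class II, were higher, but Psmb8 (-1.03, SE 0.345), a further subunit outside the rule for named genes, was called lower. H2-Q7 (-1.09, SE 0.323), H2-Oa (-1.39, SE 0.351) and Nlrc5 (-1.54, SE 0.432), an activator of MHC class I genes, were lower. The calls of H2-DMa and H2-Oa were kept in 5 and 6 of 13 alternatives, and H2-Oa turned to 0.74 without the Aire-high clusters. Camera did not separate the list (adjusted p = 0.274). Macrophage markers were lower in cTEC-like than in mTEC-like cells, as given under the second comparison. RNA of macrophages as a part of these differences was not tested.

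Of 31 growth signals, 4 were higher and 12 lower (19 adjusted over the list alone), and camera did not separate the list (adjusted p = 0.0521, and adjusted p = 0.393 with an estimated correlation). Fry placed the list lower (fry adjusted p = 0.00187). Tgfbr2 (2.18, SE 0.564), Ltbr, the lymphotoxin receptor (1.37, SE 0.291), and Wnt4 (1.37, SE 0.473) were higher. The Wnt4 call was kept in 2 of 13 alternatives, with a log2 fold down to 0.15 and an adjusted p up to 0.884. That of Tgfbr2 was kept in 9 of 13, with a log2 fold down to 1.21 and an adjusted p up to 0.157. Kit was 53.5-fold lower (counting interval 9.55 to 2119), Pdgfb 65.6-fold lower (11.7 to 2596) and Wnt5a at least 7.13-fold lower, against 1, 1 and 0 counts. Of 18 dissociation stress genes, 0 were higher and 5 lower (6 adjusted over the list alone), among them Klf6 (-1.13, SE 0.282), Egr1 (-1.35, SE 0.434) and Dusp1 (-1.55, SE 0.363). Egr1 turned to 0.38 at resolution 0.5. Camera placed the stress list lower (adjusted p = 0.0371, and adjusted p = 0.623 with an estimated correlation).

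Over all lists 48 of 178 genes were called in this comparison (55 adjusted over the list alone), and all 48 moved alike in both libraries. The count fell to 30 at resolution 2 and to 27 with list genes kept in the clustering. Over all 11944 genes, 953 were higher and 1737 lower. The mTEC-like class drew on different clusters in the 2 libraries, mainly the first Aire-high and the Ccl21a-high cluster in library 1 and the second Aire-high cluster in library 2. Without the Aire-high clusters, 56 genes were called, of which 24 were shared with the 48. In that version Cd40 was higher (1.65, adjusted p = 0.0338, range over alternatives 3.91e-04 to 0.548), Foxn1 was called (1.67, adjusted p = 0.0316, range 0.0162 to 0.785), and so were E2f2 (1.84, adjusted p = 0.0113, range 0.0113 to 0.564) and 17 G2/M genes. Foxn1 was also called without the low-count filter (1.00, adjusted p = 0.0162), and E2f4 by the DESeq2 Wald test (0.71, adjusted p = 0.0330, range 0.0330 to 0.488). Among called named genes with over 3 counts in each group, libraries 1 and 2 differed by over 1.5 times from the fit for Fgf21 (-6.66 and -2.31), Cdkn2a (-6.50 and -2.26), H2-Q7 (-1.64 and -0.67), Nlrc5 (-1.79 and -0.81) and Wnt4 (1.93 and 0.57), and among named genes not called for Foxn1, E2f4 (0.92 and 0.32), E2f5 (-0.51 and -1.91), E2f8 (0.89 and -1.29), E2f3 (-0.05 and 0.29) and Rb1 (0.06 and -0.21). Of the 27 called named genes, 7 kept their call in every alternative that gave a test: Cxcl12, Ccl25, Pax1, Ccl19, Psmb9, Pdgfb and Klf6.

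**Figure D2:**
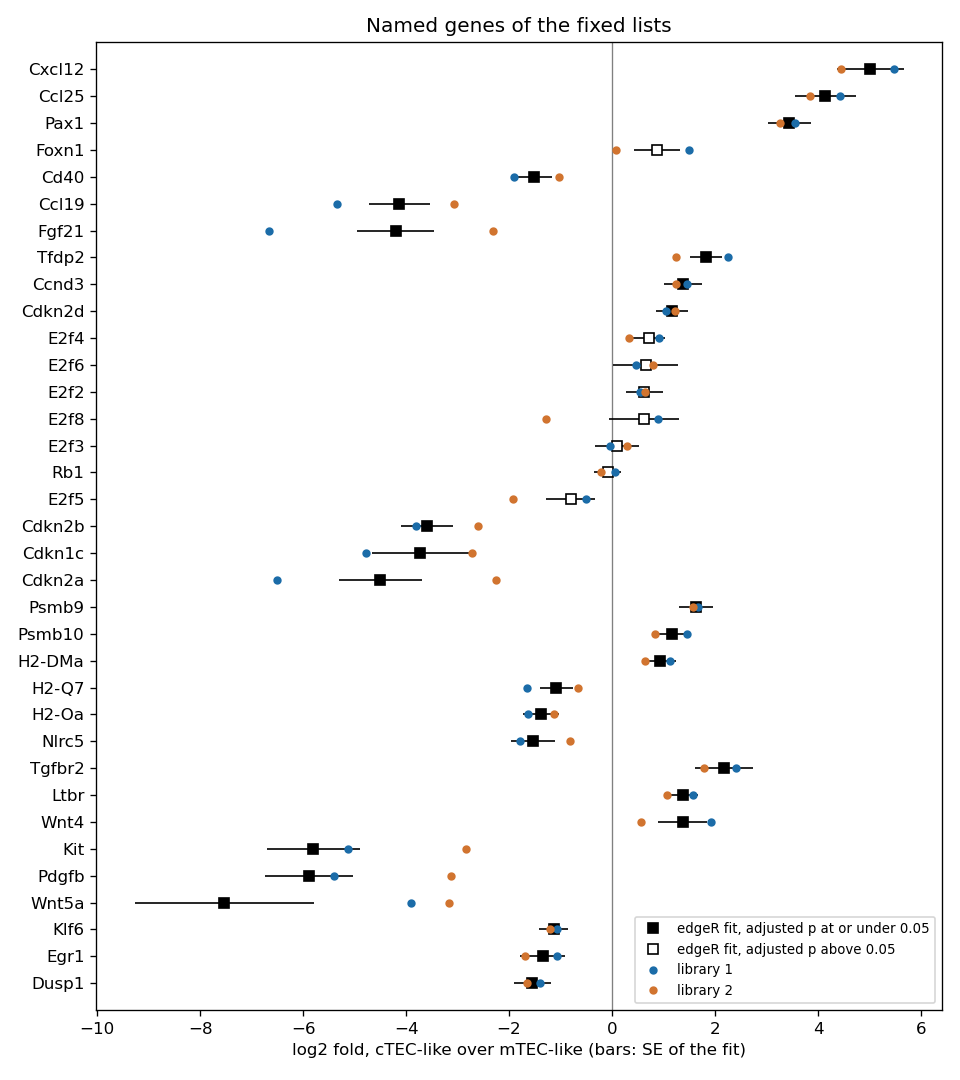
Log2 fold of the named genes, cTEC-like over mTEC-like cells, with the edgeR fit as squares (bars, SE) and the value of each library as circles. Cxcl12 stands at 5.01 and Ccl19 at -4.13 with both libraries on the same side of 0, and the library values of Foxn1 are 1.49 and 0.07, while the fitted Kit, Pdgfb and Wnt5a values rest on at most 1 count in cTEC-like cells and depend on the prior count.

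The second comparison set thymic epithelium against fibroblast-like cells, the mesenchyme that feeds it growth factors. Epithelium was higher for Foxn1 by 7.57 log2 units (SE 0.641, edgeR adjusted p = 1.06e-07), for Pax1 by 7.04 (SE 0.529) and for Ccl25 by 6.60 (SE 0.662). Ligands that act on epithelium were lower in it than in fibroblast-like cells: Fgf7 stood at -4.98 (SE 0.482), Bmp4 at -5.05 (SE 0.529) and Fgf10 at -5.47 (SE 0.432). Of 23 thymopoiesis genes 14 were higher and 7 lower in epithelium (21 adjusted over the list alone). Camera gave an adjusted p = 2.64e-04 for this list, and adjusted p = 0.0937 with an estimated correlation.

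Of the cell cycle genes many were called higher in epithelium. All but 1 of the 28 G2/M genes were called higher (27 higher, 0 lower, 27 adjusted over the list alone), among them Ube2c at 5.06 (SE 0.811), Cdk1 at 4.13 (SE 0.742) and Ccnb1 at 4.03 (SE 0.660). The exception was Foxm1 at 1.00. The median over this list was 1.86 in library 1 and 2.99 in library 2, and camera gave an adjusted p = 2.07e-05 (adjusted p = 0.523 with an estimated correlation). Not all epithelium shared this excess. Cells scored for G2/M genes were 12.2% and 20.4% of the first Aire-high cluster and 12.2% and 20.6% of the second. In cTEC-like cells the shares were 7.23% and 55.2%. The Ccl21a-high cluster had 0.529% and 1.48%, below the 1.10% and 3.40% of fibroblast-like cells. An unnamed cluster mixing fibroblast and mTEC markers, with Ccl21a and Krt5 among its leading genes, had 3.33% and 17.8%. Its median library 2 cell had 1428.5 UMIs, against 7364 in the Ccl21a-high cluster. The low library 2 share of the Ccl21a-high cluster thus covers only the deeper cells that kept the name. Of 32 G1/S genes 14 were higher and 0 lower (14 adjusted over the list alone), led by Rrm2 at 3.76 (SE 0.569), Hells at 2.14 (SE 0.494) and Uhrf1 at 2.11 (SE 0.601). The Cdk1 call was kept in 15 of 15 alternatives, those of Ube2c and Rrm2 in 13, Hells in 12, Ccnb1 in 11 and Uhrf1 in 10. Camera gave an adjusted p = 0.0353 for G1/S genes (adjusted p = 0.674 with an estimated correlation). Thymocyte markers summed to 104 and 349 CPM in fibroblast-like cells, below both epithelial classes. The naming of clusters also bears on the G2/M excess. A library 1 cluster with 8 of 9 fibroblast markers raised, unnamed for its size, had 15 of 16 cells scored for G2/M genes. Fibroblast-like cells had 15 of 1359 in that library. Unnamed clusters mixing fibroblast and thymocyte markers had 209 of 266 and 340 of 985 in library 2, against 25 of 736 fibroblast-like cells. The median fibroblast-like cell of library 2 had 6589 UMIs, against 2012 in cTEC-like and 2512.5 in mTEC-like cells. The classes compared thus differ in depth and in thymocyte markers. The comparison with these clusters in the fibroblast-like class was not tested.

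Of 25 E2F and Rb network genes, 7 were higher and 2 lower (6 adjusted over the list alone). E2f8 (2.18, SE 0.614), Tfdp2 (1.86, SE 0.287), E2f2 (1.44, SE 0.308) and Rb1 (1.15, SE 0.230) were higher in epithelium. Thymocyte markers were also higher in both epithelial classes, and thymocyte RNA as a part of these values was not tested. Rbl2, an Rb relative (-0.78, SE 0.235), and Ccnd1 (-1.32, SE 0.441) were lower. The calls of E2f8, E2f2 and Ccnd1 were kept in 10, 9 and 9 of 15 alternatives. E2f4 (-0.01), E2f3 (-0.07), E2f5 (-0.17) and E2f6 (-0.81, edgeR adjusted p = 0.168) were not called. E2f6 was called without the low-count filter (-1.02, adjusted p = 0.0268) and, for all named epithelial cells pooled, under stricter cell filters (-1.40, adjusted p = 0.00595), with an adjusted p up to 0.518 in other alternatives. Camera did not separate the network (adjusted p = 0.469), while fry placed it higher (fry adjusted p = 0.0245).

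Antigen presentation had the lowest camera p of the 7 lists in this comparison (adjusted p = 1.50e-13, and adjusted p = 0.0676 with an estimated correlation). Of 21 genes 18 were higher and 1 lower (20 adjusted over the list alone). Cd74, the MHC class II chaperone, was higher by 7.15 (SE 0.455), H2-Ab1 by 6.86 (SE 0.481) and H2-Aa by 6.84 (SE 0.477), while Tapbp, the tapasin of MHC class I loading, was lower (-0.68, SE 0.240). The Tapbp call was kept in 10 of 15 alternatives. Markers of other cells with MHC class II also differed: macrophage markers summed to 5.76 and 69.5 CPM in cTEC-like, 510 and 545 CPM in mTEC-like and 4.45 and 7.81 CPM in fibroblast-like cells, dendritic markers to 5.76 and 5.96, 42.2 and 26.8, and 2.65 and 2.34 CPM, and B cell markers to 65.7 and 119, 73.2 and 73.7, and 672 and 801 CPM. Of 31 growth signals, 5 were higher and 19 lower (24 adjusted over the list alone). Wnt4 (6.53, SE 0.598), Tnfrsf11a, the receptor RANK (4.15, SE 0.484), and Ltb (3.48, SE 0.465) were higher in epithelium. Fgfr1 (-6.18, SE 0.452) was lower, and so were Fgf2 by 22.5-fold and Wnt5a by 11.7-fold in pooled epithelial counts, since with 1 and 0 cTEC-like counts their fits depend on the prior count. Camera did not separate the growth signals (adjusted p = 0.0590, and adjusted p = 0.407 with an estimated correlation), while fry placed them lower (fry adjusted p = 6.76e-04).

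Of 18 dissociation stress genes, 0 were higher and 10 lower in epithelium (12 adjusted over the list alone). Dusp1 stood at -2.04 (SE 0.284), Fos at -2.08 (SE 0.361) and Egr1 at -2.42 (SE 0.351). Camera gave an adjusted p = 0.0176 (adjusted p = 0.590 with an estimated correlation). In all, 124 of 178 list genes were called (128 adjusted over the list alone), 85 higher and 39 lower, all 124 in the same direction in both libraries. Over all genes 2645 were higher and 2613 lower. Among called named genes with over 3 counts in each group, the libraries lay over 1.5 times from the fit for E2f8 (2.09 and 0.57), Ccnd1 (-2.39 and -0.63), Cdk1 (2.62 and 4.64) and Ccnb1 (2.06 and 4.36), and among those not called E2f5 (0.10 and -0.88) and E2f4 (0.07 and -0.15) changed sign. Of the 31 called named genes, 19 kept their call in every alternative, of which 2 of 15 pooled all named epithelial cells in place of the mean of both classes. The count fell to 80 under looser cell filters and to 81 without the 1% minimum of the clustering.

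The third comparison set thymic epithelium against endothelial-like cells, through which progenitors enter the thymus. Epithelium was higher for Cd40 (at least 30.5-fold), Ccl25 (5.87 log2 units, SE 0.679), Il7, the cytokine for thymocyte survival (4.40, SE 0.5997), and Foxn1 (4.10, SE 0.673, edgeR adjusted p = 2.28e-04). Endothelial-like cells were higher for Bmp4 (-2.92, SE 0.755), Kitl (-3.08, SE 0.318) and Cxcl12 (-3.52, SE 0.467). Of 23 thymopoiesis genes 13 were higher and 6 lower (19 adjusted over the list alone), and camera gave an adjusted p = 0.0139 (adjusted p = 0.149 with an estimated correlation).

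Of 25 E2F and Rb network genes, 4 were higher and 1 lower (2 adjusted over the list alone). Cdkn2b was 57.1-fold higher in epithelium (counting interval 10.2 to 2258, against 1 count), Tfdp1 higher by 1.34 (SE 0.450) and Cdk4 by 1.10 (SE 0.392), and Ccnd1 was lower (-1.59, SE 0.478). Their calls were kept in 9, 10, 10 and 10 of 15 alternatives. No E2F factor was called: the fits were 0.68 for E2f2, -0.01 for E2f3, -0.32 for E2f4, -0.64 for E2f5 and -0.22 for E2f6, and E2f8 had a ratio of 1.80 (counting interval 0.5998 to 8.86). Rb1 stood at 0.00 with an SE of 0.266. Camera did not separate the network (adjusted p = 0.469).

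Of 28 G2/M genes 3 were higher and 0 lower (1 adjusted over the list alone): Ube2c (2.65, SE 0.926, edgeR adjusted p = 0.0423), Cks2 (2.53, SE 0.585) and Top2a (1.72, SE 0.612). Their calls were kept in 2, 14 and 5 of 15 alternatives, with Ube2c down to 0.55 and Top2a down to 0.46. Camera gave an adjusted p = 0.0257 (adjusted p = 0.674 with an estimated correlation), and 0 G2/M genes were called without the Aire-high clusters. Of 32 G1/S genes edgeR called 0 (0 adjusted over the list alone, 5 at an unadjusted p under 0.05), and DESeq2 called 0 (camera adjusted p = 0.152). Thymocyte markers summed to 185 and 1023 CPM in endothelial-like cells.

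Of 21 antigen presentation genes 11 were higher and 0 lower (11 adjusted over the list alone; camera adjusted p = 4.85e-06, and adjusted p = 0.149 with an estimated correlation). H2-Oa was 101-fold higher in epithelium (counting interval 28.0 to 835), H2-DMb2 higher by 5.36 (SE 0.475) and H2-Aa by 3.87 (SE 0.411). Of 31 growth signals 6 were higher and 10 lower (17 adjusted over the list alone). Hgf was at least 2.88-fold higher, Bmp7 12.4-fold higher (3.40 to 102) and Wnt4 higher by 3.21 (SE 0.559). In pooled epithelial counts Igf2 was 4.00-fold, Pdgfb 7.76-fold and Kdr, the VEGF receptor, 1266-fold lower, since with 1, 1 and 3 cTEC-like counts their fits depend on the prior count. Camera did not separate the growth signals (adjusted p = 0.0679, down), while fry placed them lower (fry adjusted p = 7.29e-04). The list's fitted median was -0.35 but its mean 0.02. With genes of 3 or fewer counts at their bound or pooled ratio the median was -0.35 and the mean -0.44.

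Of 18 dissociation stress genes, 0 were higher and 13 lower in epithelium (14 adjusted over the list alone), with Dusp1 at -2.37 (SE 0.291), Fos at -2.37 (SE 0.363) and Ier3 at -2.75 (SE 0.304). Camera gave an adjusted p = 5.25e-05 (adjusted p = 0.389 with an estimated correlation). In all, 67 of 178 list genes were called (68 adjusted over the list alone), 37 higher and 30 lower, all 67 in the same direction in both libraries. Over all genes 1488 were higher and 1671 lower. Among called named genes with over 3 counts in each group, the libraries lay over 1.5 times from the fit for Il7 (7.50 and 3.18), Foxn1 (7.68 and 2.80), Bmp4 (-4.23 and -0.98), Ccnd1 (-2.87 and -0.63), Top2a (2.34 and 1.08) and Wnt4 (5.26 and 2.10), and among those not called E2f5 (0.35 and -1.78), E2f6 (-0.41 and 0.11), E2f3 (-0.15 and 0.15) and Rb1 (-0.34 and 0.45) changed sign. Of the 26 called named genes, 14 kept their call in every alternative, with the same 2 pooled alternatives among the 15. At 3 counts or fewer in endothelial-like cells stood 20 of the 178 genes, 8 of them at 0.

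Cells carrying G2/M transcripts were then counted per class at 1000 UMIs per cell. In library 1 the share was 7.23% of cTEC-like cells (exact 95% interval 2.70 to 15.1), 7.32% of mTEC-like cells, 1.10% of fibroblast-like cells, 4.44% of endothelial-like cells and 17.1% of thymocyte-like cells. In library 2 it was 55.2% of cTEC-like cells (47.2 to 63.0), 16.9% of mTEC-like cells, 3.40% of fibroblast-like cells, 21.4% of endothelial-like cells and 63.1% of thymocyte-like cells. Tuft-like mTEC had 1.49% in library 1 and 42.4% in library 2, and keratinocyte-like mTEC 0 of 32 cells, which allows up to 9.38%, and 30.3%. Within the mTEC-like class the Ccl21a-high cluster had 0.529% and 1.48%. Thymocyte markers also differed between the libraries, with 90.0 and 1652 CPM in tuft-like and 98.4 and 1366 CPM in keratinocyte-like mTEC. Markers of other cells rose as well. Fibroblast markers went from 299 to 1515 CPM in cTEC-like cells, from 508 to 2929 CPM in tuft-like and from 225 to 2975 CPM in keratinocyte-like mTEC, and erythroid markers from 3.46 to 699, from 17.8 to 154 and from 15.3 to 3781 CPM. RNA from thymocytes or other cells in the same barcodes stays open, and these shares alone do not measure cycling.

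**Figure D3:**
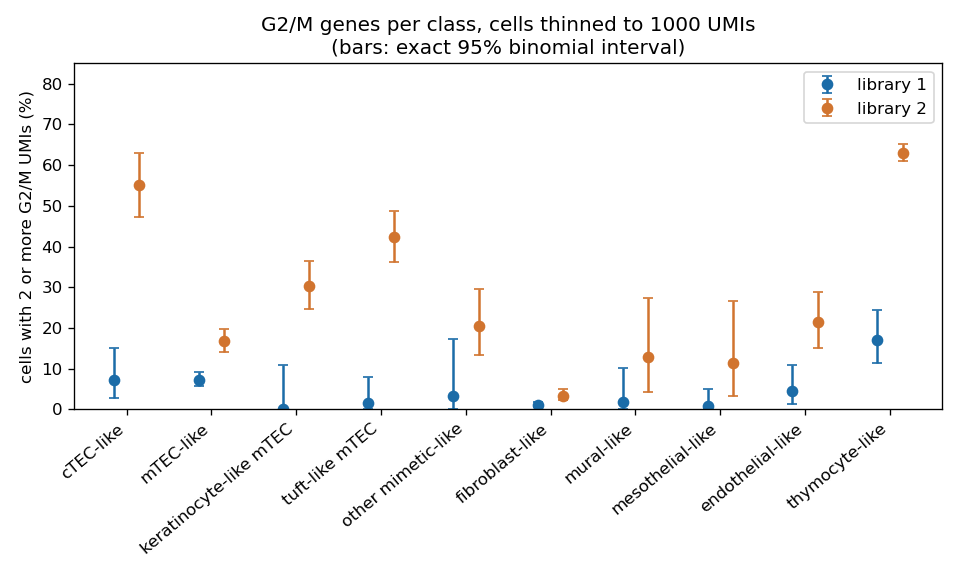
Percent of cells with 2 or more UMIs over the G2/M list per class, with each cell thinned to 1000 UMIs, a point per library and exact 95% binomial bars. The cTEC-like points stand at 7.23% and 55.2%, the fibroblast-like points at 1.10% and 3.40%, and the thymocyte-like points at 17.1% and 63.1%.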

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

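The test of spread between barcodes in this part was chosen only after the clusters had been seen, and refined to its present form after first results.

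An unnamed epithelial cluster led by Scn1a, Ackr4, Ptprz1, Nrtn and Trpm3 carried Foxn1 although it enters no comparison. Without thinning, a Foxn1 UMI was found in 15.7% of its cells in library 1 (19 of 121, median 9677 UMIs) and 10.1% in library 2 (9 of 89, median 5029 UMIs), against 0.736% and 0.272% of fibroblast-like cells. A count of 0 in as many cells would allow 2.48% and 3.37%, which is no measure of background. At 1000 UMIs per cell the shares were 5.79% (2.36 to 11.6) and 3.37% (0.701 to 9.54), the second at that limit and not above it. Its Foxn1 level was 31.7 and 42.3 CPM. It expressed Trp63, a regulator of epithelial progenitors, at 373 CPM against 40.9 CPM in other cells, Isl1 at 271 against 29.5 CPM, and Ackr4, an atypical chemokine receptor, at 238 against 10.1 CPM. Epcam stood at 493 CPM, Krt5 at 342 CPM and Krt14 at 357 CPM. It took 3.37% of library 1 and 1.09% of library 2.

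A second signal outside the comparisons came from 20 small clusters made almost only of library 2 barcodes, with 864 cells or 10.6% of that library. Several were led by genes of tissues other than the thymus, such as Ins2 (insulin), Cryba1 (a lens crystallin), Pomc and Ppy (hormones), Try4 (a trypsin) and Scgb1a1 (an airway secretoglobin).

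Barcodes that share a single pool of RNA are a candidate explanation for these clusters. Between barcodes thinned to 1000 UMIs, the variance of gene counts over their mean had a median of 0.908 across the small clusters (0.875 to 1.08), while the lowest of 22 library 1 clusters was 0.974, and 18 of the 20 lay below it. Of the other library 2 clusters 5 of 26 also lay below, so a property of library 2 as a whole may add to it. Counts simulated from a single pool gave 0.933 for the small cluster at 0.875 and 0.929 for that at 1.08. The spread of the small clusters thus reached below and above that of such a simulated pool. Free RNA of library 2 at large stays open, since leading genes are picked for their fold and cannot test it. Whether such a pool was a single cell, a clump or a damaged droplet stays open. No biological explanation was tested, and this includes expression of such genes by medullary epithelial cells themselves.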

How the results depend on the processing

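Among the alternatives in this part, clustering without scaling or without the 1% minimum, removal of the highest doublet scores, and mTEC-like cells without Aire-high clusters were chosen after seeing the data. Counts of called list genes stayed within 1.5 times of the reported count in 11 of 13 alternatives for cTEC-like against mTEC-like (27 to 56), 13 of 15 against fibroblast-like (80 to 131) and 15 of 15 against endothelial-like cells (46 to 83). The exceptions were 30 at resolution 2 and 27 with list genes kept in the clustering, against 48, and 80 under looser filters and 81 without the 1% minimum, against 124. Without the library block, 43, 109 and 62 genes were called, 42, 109 and 62 of them shared with the reported calls. Camera called 11 of 21 tests, and 0 with an estimated correlation. The mTEC-like Foxn1 level became 75.4 CPM at resolution 2, 77.8 with doublets kept, 73.2 with list genes kept and 62.7 without Aire-high clusters. The share of mTEC-like cells with a Foxn1 UMI became 8.70% under stricter filters, 4.82% with doublets kept, 4.998% with list genes kept, 5.40% with each library clustered alone, 6.87% without the highest doublet scores, 3.73% without Aire-high clusters and 30.7% unthinned, and that of cTEC-like cells 50.2% unthinned. The cTEC-like share of cells became 4.67% at resolution 0.5, 1.88% under looser filters, 1.39% with each library clustered alone (0 in library 1), 2.38% without the highest doublet scores and 2.53% of stromal cells. The mTEC-like G2/M share was 1.01% without Aire-high clusters and 30.1% at 1 UMI. Other values moved by over 1.5 times but within the SD of the libraries. The cTEC-like Foxn1 level was 129 CPM at resolution 0.5 and its share with a Foxn1 UMI 9.71% there and 10.4% under looser filters. The mTEC-like share of cells was 9.002% at resolution 2, 8.93% with doublets kept, 10.7% with list genes kept, 9.20% with each library clustered alone and 6.09% without Aire-high clusters, and the fibroblast-like share 38.0% at resolution 0.5 and 41.0% with list genes kept. At 1 and 3 G2/M UMIs the cTEC-like share was 48.6% and 19.6%, and at 3 the mTEC-like share 7.06%. For named genes, 1274 of 1475 values kept direction and side of the threshold, 35 changed sign with neither value called, 152 lost and 6 gained a call, and 8 changed the sign of a called gene. These 8, all in cTEC-like against mTEC-like, were Cd40 at 1.65, Cdkn2b at 0.34 and H2-Oa at 0.74 without Aire-high clusters, Cdkn1c at 0.69 and Egr1 at 0.38 at resolution 0.5, Cdkn1c at 0.53 under looser filters, and H2-Oa at 0.029 at resolution 2 and 0.10 with doublets kept. Unthinned shares moved because deeper cells show more UMIs, and for the other changes the cause was not tested. Keeping doublets restored only the 1 called cell (11774 against 11773 cells). The values it moved therefore show how far clustering and naming shift with 1 cell, not an effect of doublets. Leaving out a library gave values with no test: cTEC-like and mTEC-like Foxn1 133 to 281 and 94.2 to 116 CPM, shares with a Foxn1 UMI 9.82% to 22.9% and 5.82% to 6.65%, class shares 1.99% to 2.31% (cTEC-like), 8.60% to 25.1% (mTEC-like), 8.99% to 37.9% (fibroblast-like) and 3.90% to 25.1% (thymocyte-like), and G2/M shares 7.23% to 55.2% (cTEC-like) and 7.32% to 16.9% (mTEC-like). Under stricter filters and with each library clustered alone, cTEC-like cells were not found in both libraries and cTEC-like against mTEC-like gave no value, and the other comparisons there used all named epithelial cells pooled, including the mimetic classes, which is a different contrast. The 2012 UMIs of the median cTEC-like cell in library 2 limit what its low genes show.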

Other observations

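The tests of cTEC-like, tuft-like or keratinocyte-like cells alone and of S100a8 and Lyz2 without a prior were chosen after the results had been seen, and the other tests in this part before. Cluster genes are given as description, since they define the clusters.

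The fibroblast-like class joined 3 clusters with different leading genes. The first, with 500 and 224 cells, was led by Fn1, Mrgprg, Smpd3, Pi16 and Mfap5, the second (480 and 310 cells) had Cxcl14, Gpm6b, Nrp1 and Col15a1 among its leading genes, and the third (379 and 202 cells) was led by Inmt, Cpxm2, Penk, C7 and Srpx. A further cluster of 389 and 156 cells, led by Sod3, Cpe, Postn, Serpine2 and Mgp, qualified for fibroblast and mural cells and stayed unnamed, with Postn, a matrix protein, at 4449 CPM against 390 CPM in other cells.

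The medullary epithelium held distinct states in both libraries. The first Aire-high cluster had Aire, the regulator of self-antigen expression, at 512 CPM, Fezf2, a second such regulator, at 483 CPM and Cd80 at 71.6 CPM. The Ccl21a-high cluster had Ccl21a, a chemokine that draws thymocytes to the medulla, at 11739 CPM, Krt5 at 1509 CPM and Krt14 at 1252 CPM. A cluster led by Ltf, Wfdc2, Gsto1, Cyp2f2 and Spink5 (24 and 148 cells) qualified for 2 mimetic types and stayed unnamed.

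G2/M transcripts in cTEC-like, tuft-like and keratinocyte-like cells were frequent in library 2 and rare in library 1. Division of these cells as 1 cause common to all 3 classes is argued against by the pooled share with 2 or more G2/M UMIs. It was 20.6% (11.5 to 32.7) in their library 2 cells with 5000 or more UMIs, against 43.3% (39.3 to 47.4) in shallower cells. In tuft-like cells alone the share was 4.17% (1 of 24, 0.105 to 21.1) against 46.3% (39.8 to 53.0). In keratinocyte-like cells alone it was 13.0% (3 of 23, 2.78 to 33.6) against 32.1% (26.0 to 38.8). These intervals overlap, so division of keratinocyte-like cells stays open. In cTEC-like cells alone the share was 56.2% (9 of 16, 29.9 to 80.2) against 55.1%, as their own division would give, while thymocyte markers were at 1018 against 2614 CPM. RNA of dividing thymocytes in the same barcodes was tested by the ratio of excess G2/M to excess thymocyte marker UMIs over that of thymocyte-like cells. The median ratio over the 3 classes was 0.759 (range 0.565 to 4.02). Intervals of single ratios come from 1000 bootstraps of cells (95%) and leave out variation between libraries. The ratio lay within the 2-fold limit in tuft-like cells (0.759, 0.627 to 0.896), as such RNA would give. The lower end for keratinocyte-like cells (0.565, 0.468 to 0.674) passed that limit. In cTEC-like cells this RNA stays open, since their ratio of 4.02 had a lower bound of 1.91 and no upper bound, and in the 16 deep cells the excess of G2/M UMIs per thymocyte marker UMI was 1.28 times the ratio in thymocyte-like cells (0.482 to 2.44), of which neither excludes 2. In cTEC-like cells their own division and thymocyte RNA cannot be told apart, RNA of other cells was not tested, and no biological explanation for the difference between libraries was tested, as both share 1 genotype.

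S100a8 and Lyz2, which neutrophils and macrophages express, were among the leading genes of the Aire-high epithelial clusters. Neutrophils and macrophages, or their RNA in the same barcodes, stay open as the source although both are CD45-positive and such cells were depleted, because the outcome of the test depended on the prior of 10 CPM in its folds. With the prior, the other 8 markers of those types had a median log2 fold of 1.69 in library 1 and 1.05 in library 2, under 0.5 times the 4.70 and 3.57 of Lyz2, the smaller of the pair, and without it 4.14 and 2.59, over 0.5 times its 5.50 and 3.86. Retnlg and Csf3r, abundant in neutrophils, stood at 30.5 and 1.37 CPM in these clusters in library 1, against 0 and 0.275 CPM in other cells, and both at 0 CPM in library 2, against 0.181 and 0.471 CPM. Expression by Aire-high epithelial cells themselves was not tested.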
